A study of Mus musculus with 5 samples.

How the data were processed

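RNA immunoprecipitation followed by microarray hybridisation (RIP-chip) was used to profile RNA recovered with a FLAG-tagged MKRN1 protein from R1 cells, a line of mouse embryonic stem cells. MKRN1 belongs to the makorin family of RING-domain zinc finger proteins. Per the labels' protocols, the lines carried either a FLAG:MKRN1 expression construct or the FLAG vector without MKRN1 (FLAG:Ctrl). Per the same protocols, both lines were thawed on mouse embryonic fibroblast feeders and then passaged on gelatin with LIF and serum to clear the feeders. Lysates, per the extraction protocol in the labels, were incubated with beads carrying anti-FLAG or IgG antibodies, and an aliquot of each lysate was kept beforehand as input. The 5 samples were grouped by their titles into 5 groups of 1 array each: the input and the anti-FLAG RIP of FLAG:Ctrl lysate, and the input, the anti-FLAG RIP and the IgG RIP of FLAG:MKRN1 lysate.

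The authors' deposited table holds 1 log2 value per probe set and array. Per the labels, RNA was labelled with biotin by standard Affymetrix procedures. The log2 scale was read from the values, which ran from 2.56 to 14.4 over the 5 arrays. The background correction, summarisation and normalization used by the authors are not given in the sources used here. The 5 columns had nearly the same medians, from 5.68 to 5.88, and no further scaling was applied for the main values. Between 6.77% and 19.2% of the genes kept for analysis had equal values (within 1e-06) on a given pair of arrays. Array signal has no read depth, and the number of arrays limits the precision.

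Of 34760 probe sets, 21640 were paired with 1 gene symbol in the platform annotation, 1321 with several, and 11799 were not named there. Gene identifiers of 21553 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which was used to update symbols and to see which genes are neighbours. The other 87 kept the symbol of the platform annotation. No coordinates are given, because no source used here names a genome build for the array values. For each of 19937 genes the probe set with the highest mean over the 5 arrays was taken. The 11502 genes whose mean was at or above the median of all probe-set means, a log2 value of 5.76, were kept.

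With 1 array per group there is no replicate error, so no test was run and no p-value is given. Each comparison is a difference of log2 values, counted at 2-fold (a log2 difference of 1). A gene was called higher in the MKRN1-labelled RIP when it was at least 2-fold above both control RIPs and above the input of the same lysate, and lower when it was at least 2-fold below both and below that input. The same rule applied to each control RIP in place of the MKRN1-labelled RIP served as a yardstick. The score of a gene is the smaller in size of its 2 differences from the control RIPs, or 0 where their signs differ. Named genes were the 15 highest and 6 lowest scores among called genes, the 6 highest and 6 lowest input differences, the 5 at either end of each other comparison described, up to 4 members per gene list with the largest difference, and the makorin genes Mkrn1, Mkrn2 and Mkrn3; 1 of the 6 lowest scores is not reported here. The groups, comparisons, call rule, naming rule and 25 gene lists were fixed before the data were examined.

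For each list, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins (seed 1). A list is described as outside the range of random lists at or below the 2.5th or at or above the 97.5th percentile. Lists with fewer than 5 kept genes were given no percentile, which left 24 lists. These percentiles describe these arrays and are not p-values; over 168 of them, about 5% would lie outside by chance.

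The calling rule and the list percentile were tested on simulated data of 11502 genes built from the real values. In that simulation, 100% of genes planted at a log2 difference of 2 or -2 from both control RIPs were called, and 91.2% at 1.5. At -1.5, 100% were called. At the threshold itself, 52.9% of genes planted at 1 and 17.6% planted at -1 were called. No gene was called in simulated arrays without change, with a noise SD of 0.172. That noise was the same for every gene and came from the difference between the 2 control RIPs, whose SD was 0.243. Differences of the MKRN1-labelled RIP from these RIPs had SDs of 0.571 and 0.550. The shares called and the absence of calls rest on that noise and give no error rate for the real arrays. Of 100 random lists of 30 genes, 5 lay outside the range, and a list moved by 0.3 lay at the 100th percentile. Alternatives covered median centring, quantile normalization, other filters on dim probe sets, the median over the probe sets of a gene, thresholds of 1.5-fold and 4-fold, each control RIP alone, and other uses of the input. Removal of the trend with signal level was added after the data were seen, as was a setting in which every value below the level filter of 5.76 was raised to it. The sources used here hold no detection calls, so that level stands in for a background and is not a measured one. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.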

Results

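RNA from 5 arrays was compared: inputs of FLAG:Ctrl and FLAG:MKRN1 lysates, an anti-FLAG RIP from each lysate, and an IgG RIP from the FLAG:MKRN1 lysate. Per the labels, the anti-FLAG RIP from FLAG:Ctrl lysate and the IgG RIP were run alongside as controls for nonspecific recovery. There were no replicates, so differences are given without an error and none has a replicate check. Across all probe sets, Pearson's r was 0.992 between the 2 control RIPs and between 0.959 and 0.967 between the anti-FLAG RIP of FLAG:MKRN1 lysate and each other array; these correlations run across probe sets, which are not independent replicates. That array also had the narrowest spread of values, with an SD of 2.19 against 2.28 to 2.35 on the other arrays.

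Mkrn1 itself was not higher in the lysate labelled FLAG:MKRN1. Its log2 value was 11.71 in the FLAG:MKRN1 input and 11.80 in the FLAG:Ctrl input, a difference of -0.09. Among the RIPs it was 12.20 from FLAG:Ctrl lysate, 11.90 in the anti-FLAG RIP from FLAG:MKRN1 lysate and 11.99 in the IgG RIP. The related genes Mkrn2 and Mkrn3 differed by -0.22 and -0.29 between the inputs. Mkrn1 had 1 probe set, and whether it covers the transcript of the construct is not known here. Because this value does not separate the lines, the anti-FLAG RIP from FLAG:MKRN1 lysate is called the MKRN1-labelled RIP throughout, and directions drawn from it rest on the label.

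The central comparison asked which RNAs were recovered with FLAG:MKRN1 beyond both backgrounds. Of the 15 highest scores, 7 belonged to small nucleolar RNAs of the Snora and Snord series, which guide modification of ribosomal and spliceosomal RNA. Snora21 was 30.0-fold above the FLAG:Ctrl RIP and 23.7-fold above the IgG RIP, a score of 4.57, or 3.37 with the median over its 2 probe sets. Snora20 was 10.7-fold and 10.9-fold above them, and Snord35a had log2 differences of 2.98 and 3.59 (3.31 with values raised to the level filter). Rnu3a, a U3 small nucleolar RNA gene that acts in ribosomal RNA processing, was 12.4-fold and 7.90-fold higher. In total 125 genes were higher than in both control RIPs and above input, against 10 when the FLAG:Ctrl RIP and 5 when the IgG RIP was put in its place. This yardstick is small by construction. A control RIP can be called only where the 2 control RIPs lie at least 2-fold apart, as 20 and 32 genes did. The contrast shows that the array of the MKRN1-labelled RIP stands apart, not why. The differences from the 2 control RIPs share the array of the MKRN1-labelled RIP and are not independent.

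Small nucleolar RNAs, taken by Snora, Snord and Scarna symbols and so without Rnu3a, made up 17 of the 125 higher genes. Of this class 39 were kept, and they lay 0.56 higher in the FLAG:MKRN1 than in the FLAG:Ctrl input. Against the FLAG:MKRN1 input the class had a median of 0.12 in the MKRN1-labelled RIP and -0.60 in the IgG RIP. Part of the difference between these RIPs therefore goes with low values in the IgG RIP. Other high scores came from Snora75 (2.57), Snord38a, which was 5.67-fold above the IgG RIP, Snora30 (2.24) and Snora44 (2.11), and from the microRNA gene Mir6516 (2.10). Protein-coding genes near the top included Depdc1a at 2.75, Tmsb15a, a beta-thymosin gene, at 2.44, the histone H3 gene H3c15 at 2.32, Wfdc15a at 2.30 and Vpreb1, which encodes part of the surrogate light chain of B-cell precursors, at 2.12. BC147527 scored 2.43, with a log2 difference of 2.43 from the IgG RIP of the same lysate; its value in the FLAG:Ctrl RIP was 4.35, below the level filter of 5.76, and against that level it was 3.81 higher. The gene farthest above the FLAG:Ctrl RIP, AF067061, was 91.5-fold higher there and only 1.79-fold above the IgG RIP, so it was not called; it lies near BC147527 and Tcstv3 in the genome, and whether these share probes is not known here. Olfactory receptor genes, a class with little use in stem cells, also lay higher in the MKRN1-labelled RIP, by a median of 0.34 and 0.26 over 35 genes. The other probe set of Depdc1a had a score of -0.02, and a second kept probe set went the same way against both control RIPs for 4 of the 13 higher genes that had one.

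More genes were lower than higher in the MKRN1-labelled RIP. Rbbp6, which encodes an RB-binding ubiquitin ligase, was 14.8-fold below the FLAG:Ctrl RIP and 16.5-fold below the IgG RIP. Timm21, a component of mitochondrial protein import, had a score of -3.68 and Dusp19, a dual-specificity phosphatase gene, -2.72; both were below the level filter in the MKRN1-labelled RIP, and with values raised to it the scores were -3.23 and -2.20. Other low scores were those of the mitotic kinase gene Pbk (-2.49) and the histone demethylase gene Kdm5a (-2.44). In total 617 genes were lower than in both control RIPs and below input. In the same role the counts were 8 for the FLAG:Ctrl RIP and 2 for the IgG RIP, which are small by construction as above. With the input of its own lysate taken from each RIP first, 118 genes were called higher and 611 lower in the MKRN1-labelled RIP. Of these, 100 and 524 were shared with its calls before. The counts were then 41 and 35 for the FLAG:Ctrl RIP and 11 and 12 for the IgG RIP. Transcript lengths were not used here, so how far these calls go with the length of the RNA is not known. An exploratory look at gene spans, described below without values, had longer genes lower on this array. The 3 probe sets of Rbbp6 had scores from -3.88 to -0.68, and a second kept probe set went the same way for 31 of the 41 lower genes that had one.

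Against each control RIP alone, 186 genes were at least 2-fold higher and 818 lower than in the FLAG:Ctrl RIP, and 176 higher and 798 lower than in the IgG RIP. The split depended on scaling. Higher genes made up 16.8% of the calls with the values as deposited, 31.9% with each array centred on its median, 30.6% after quantile normalization and 30.9% after removal of the trend with signal level. Centring moved the median of all genes from -0.03 to 0.14 against the FLAG:Ctrl RIP and from -0.00 to 0.14 against the IgG RIP.

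**Figure D1:**
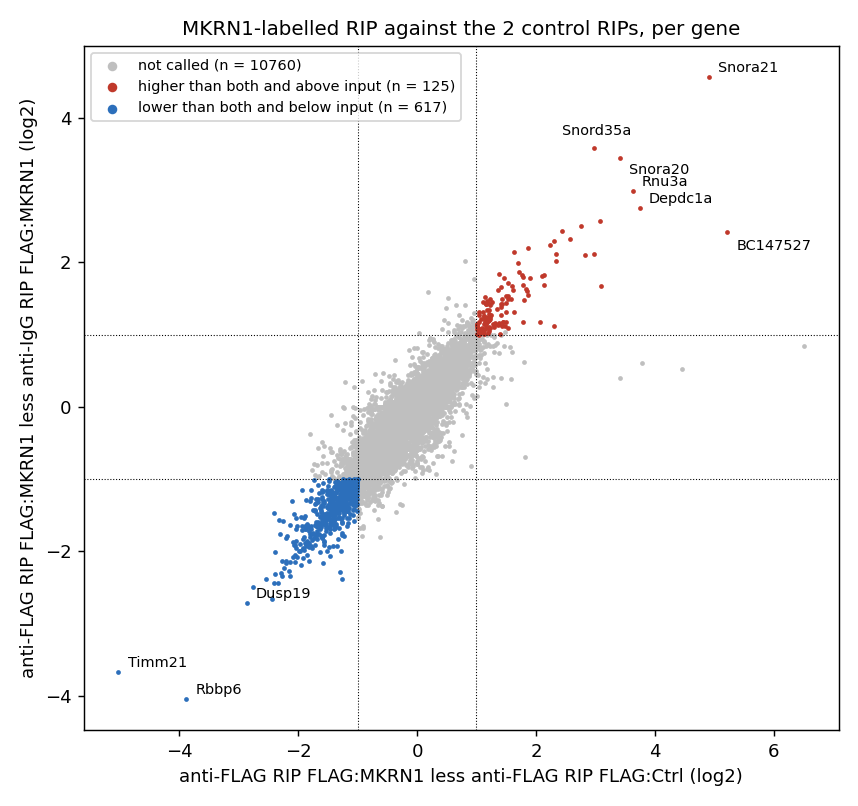
Each point is 1 of 11502 genes, with its log2 difference between the MKRN1-labelled RIP and the FLAG:Ctrl RIP on the x axis and between the MKRN1-labelled RIP and the IgG RIP on the y axis; dotted lines mark 2-fold. The 125 genes called higher are red and the 617 called lower are blue, with Snora21 at 4.91 and 4.57 and Timm21 at -5.02 and -3.68.

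Replication-dependent histone genes, which are transcribed in S phase, lay lowest of the fixed lists in the MKRN1-labelled RIP. Their median differed by -0.91 from the FLAG:Ctrl RIP and -0.82 from the IgG RIP, both at the 0.00th percentile of random lists. Of 22 kept histone genes, 10 were called lower and 1 higher. H2bc3 had log2 differences of -2.39 and -2.32 from the 2 control RIPs, H2bc14 -2.28 and -2.14, and H4c4 -1.86 and -1.93. Histone genes have near-identical copies whose signal an array may not separate, so values of single members are uncertain, and H3c15, which was not on the list, was among the highest scores.

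Genes of the cell cycle and of DNA replication were also lower than in the control RIPs. The cell cycle list had medians of -0.64 (0.06th percentile) against the FLAG:Ctrl RIP and -0.54 (0.60th percentile, and 2.55th with the trend with signal level removed) against the IgG RIP, with 7 of 36 genes called lower. Its medians shrank to -0.385 and -0.305 after quantile normalization. Cdk6, a G1 kinase gene, differed by -2.08 and -1.92, the spindle checkpoint gene Bub1b by -1.59 from the FLAG:Ctrl RIP, and the mitotic kinesin gene Kif11 by -1.22 and -1.29, though its score was -0.93 after quantile normalization. Cdkn1b, which encodes the cyclin-dependent kinase inhibitor p27, was the 1 member called higher, at 1.76 and 1.83, but its other probe set scored 0.01. The DNA replication and repair list had medians of -0.60 (0.27th percentile) and -0.63 (0.09th percentile), with 10 of 41 called lower, among them Brca2 (score -1.78), Rfc4 (-1.57), Orc1 (-1.54) and the damage-response kinase gene Atm (-1.41). The medians of this list were -0.36 and -0.41 after quantile normalization.

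Proteasome and ubiquitin genes had medians of -0.50 (0.59th percentile) and -0.47 (0.84th percentile, and 2.65th with the trend with signal level removed), and 4 of 35 were called lower: Psmb2, Psmb7, Psmc1 and Psmc5, with scores from -1.28 to -1.08. After quantile normalization the list medians were -0.32 and -0.27, and only Psmb2 of these 4 genes stayed at least 2-fold lower. With arrays centred Psmb2 and Psmb7 did. Endoplasmic reticulum stress genes lay outside the range against the FLAG:Ctrl RIP only, with medians of -0.42 (2.27th percentile, and 2.85th with arrays centred) and -0.31 (10.2th percentile). These medians shrank to -0.25 and -0.05 after quantile normalization. The 4 of 27 called lower were the stress sensor gene Atf6 at -1.81, Dnajc3 at -1.26, the chaperone gene Hspa5 at -1.21 and Hyou1 at -1.07; after quantile normalization the last 3 lay between -0.98 and -0.95, short of 2-fold. The long noncoding RNA list had medians of -0.74 (0.41th percentile) and -0.33 (13.0th percentile), with Rian and Malat1 called lower among 9. The first median lay within the range, at the 5.80th percentile, with no filter on dim probe sets. It also did so, at the 17.1th, with values raised to the level filter, where Rian was no lower than in the FLAG:Ctrl RIP (0.00). Small nucleolar RNA host genes (Snhg), noncoding RNAs grouped by symbol after the data were seen, went the other way. Their 5 kept genes, Snhg5 and Snhg11 of the list among them, had medians of 0.48 (99.5th percentile) and 0.16 (89.9th percentile), with 2 called higher and 0 lower. In the adhesion and surface list, 6 of 33 genes were called lower, including the BMP receptor gene Bmpr1a at -2.13, the integrin gene Itga6 at -1.82, the gp130 cytokine receptor gene Il6st at -1.39 and the growth factor receptor gene Igf2r at -1.23, while the list medians of -0.31 and -0.39 stayed within the range.

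Cytosolic ribosomal protein genes lay above most random lists. Their medians of -0.02 and -0.04 lay at the 98.5th and 98.1th percentiles, and none of 53 was called. Rpl21 was highest at 0.74 against each control RIP, but -0.35 with the median over its probe sets, and the lowest were Rpl10 at -0.78 against the FLAG:Ctrl RIP and Rpl29 at -0.91 against the IgG RIP. The score of Rpl10 went from -0.78 to -0.28 with the median over its probe sets. With each array centred the medians were 0.15 and 0.10, and after quantile normalization the percentiles were 76.8 and 60.9, within the range. Oxidative stress genes had a median of 0.07 (99.0th percentile) against the FLAG:Ctrl RIP and -0.01 (89.7th percentile, and above 0 after either rescaling) against the IgG RIP; the ferritin light chain gene Ftl1 was the 1 of 21 called higher, at 1.54 and 1.49. Immediate early genes lay at 0.13 (98.8th percentile) against the IgG RIP and at -0.02 (60.1th percentile, and 0.14 when centred) against the FLAG:Ctrl RIP; none of 25 was called, and with the filter at the 75th percentile the first value lay within the range, at the 94.6th percentile.

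The pluripotency network did not stand apart. Its medians of -0.16 and -0.11 lay at the 74.8th and 84.0th percentiles, with the sign changed by centring to 0.01 and 0.03, and 1 of 29 genes was called, the telomere and replication timing factor gene Rif1 at -1.61. Other members with large differences were Tbx3 at -1.74 against the FLAG:Ctrl RIP and -0.79 against the IgG RIP, and Utf1 at -1.17 and -0.80. The mRNA-binding protein, p53 and apoptosis, chaperone, translation factor, oxidative phosphorylation, glycolysis, cholesterol, secreted, feeder and lineage lists also stayed within the range against both control RIPs. The 2-cell-like list had 2 kept genes and was given no percentile. Members called lower included Pum2 (-1.05), the death receptor gene Tnfrsf10b (-1.24), Apaf1 of the apoptosome (-1.13), Cct3 (-1.03), Eif3a (-1.08), Sdhd (-1.21), the laminin gene Lamc1 (-1.12), Krt8 (-1.59) and Peg10 (-1.47). Of these, Pum2, Cct3, Eif3a and Lamc1 were short of 2-fold after centring and after quantile normalization, and Apaf1 after centring.

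**Figure D2:**
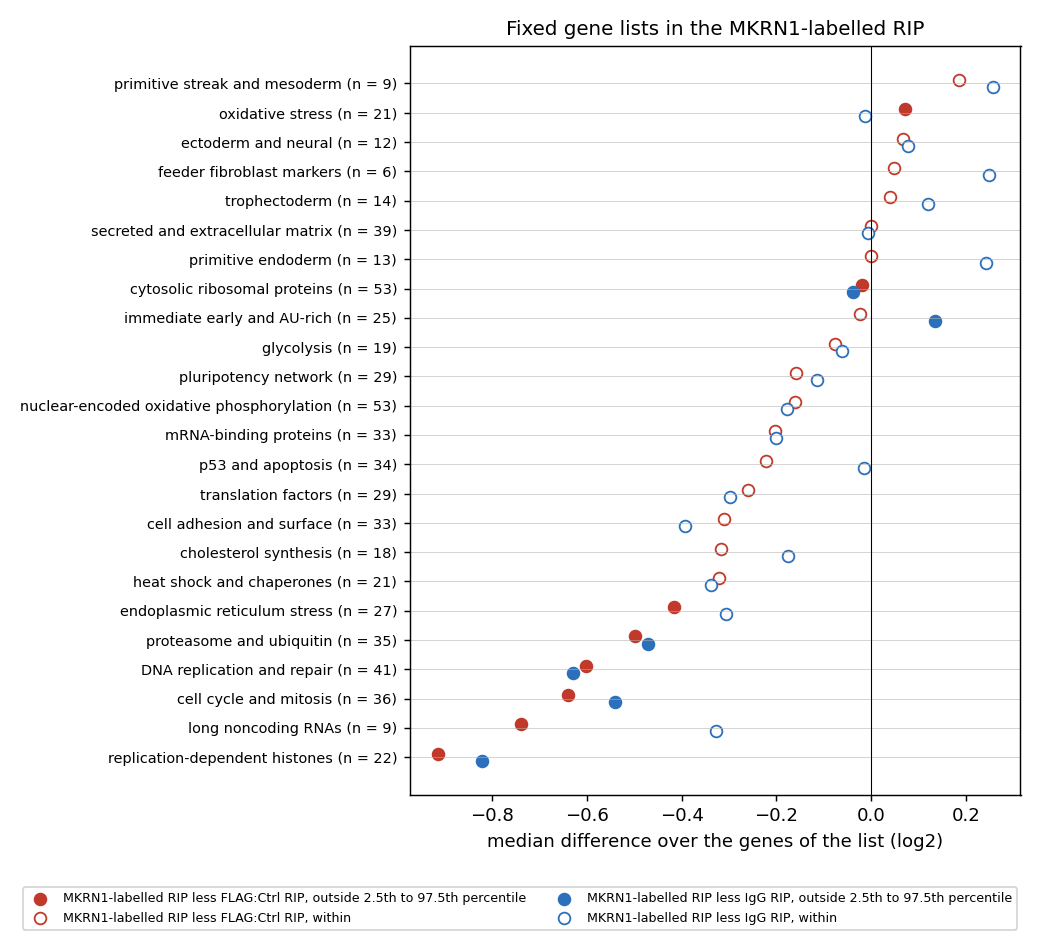
Each row is 1 of 24 fixed gene lists, with n the number of kept genes, and the x axis gives the median log2 difference of the MKRN1-labelled RIP from the FLAG:Ctrl RIP (red) and from the IgG RIP (blue); filled points lie outside the central 95% of matched random lists. Signs near 0, such as those of ribosomal, pluripotency and glycolysis genes, change when arrays are centred.

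Set against its own input, the MKRN1-labelled RIP held 284 genes at least 2-fold higher and 634 lower. The highest values relative to input were Snora21 at 4.41, Tmsb15a at 3.61 (3.36 with values raised to the level filter), BC147527 at 3.50, Depdc1a at 3.45 and H3c15 at 3.26. With the median over probe sets, Snora21 was 2.99, Depdc1a 1.52 and Rbbp6 -1.80 relative to input. The lowest values were DQ267102 at -3.83, Rbbp6 at -3.80, Gdap10 and Snord73b at -3.59 each, and the imprinted noncoding RNA Rian at -3.21, of which Gdap10 was -3.37, Snord73b -2.95 and Rian -1.59 with values raised to the level filter. Histones again lay lowest, with a median of -1.51 (0.00th percentile) and 14 of 22 genes at least 2-fold below input. That input lay above the FLAG:Ctrl input in histones, by a median of 0.28. Histones also lay below it in the IgG RIP, at -0.19 (0.00th percentile). Adhesion and surface genes had a median of -0.49 (0.03th percentile), with 9 of 33 at least 2-fold lower. Cell cycle genes at -0.30 (3.83th percentile), DNA replication and repair genes at -0.30 (6.26th percentile) and proteasome genes at -0.13 (26.2th percentile) stayed within the range against input, the last with none of 35 at least 2-fold lower.

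The control RIPs changed less from their inputs. In the FLAG:Ctrl RIP 109 genes were at least 2-fold higher and 43 lower than in its input, and in the IgG RIP 152 and 53. Rian at -3.81 (-3.49 with values raised to the level filter) and Nynrin at -3.28 (-0.65 with the median over its probe sets) were lowest in the FLAG:Ctrl RIP relative to input, followed by Snora69 at -2.30, Snora44 at -2.29 and Gnrh1 at -2.13 (-1.64 with values raised). Its highest were Snora7a at 2.87, AF067061 at 2.06 (0.18 with values raised to the level filter), Acbd7 at 1.91 (1.49), the testis cytochrome c gene Cyct at 1.86 and the myosin light chain gene Myl9 at 1.75. In the IgG RIP the Y RNA gene Rny1 was lowest at -3.02, followed by AY512931 at -2.34, DQ267102 and Snord73b at -2.25 each, and Snord35a at -2.04 (-1.76 with values raised). Its highest were Spata24 at 2.47, the meiotic genes Meiob at 2.33 (1.57 with values raised to the level filter) and Rec114 at 1.91, 6720489N17Rik at 2.31 and Hddc2 at 1.98.

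In these backgrounds DNA replication and repair genes lay above input, by a median of 0.29 (99.9th percentile) in the FLAG:Ctrl RIP and 0.28 (99.6th percentile) in the IgG RIP. Proteasome genes lay at 0.20 (96.9th percentile) and 0.30 (99.95th percentile). Long noncoding RNAs lay below input, at -0.47 (0.00th percentile) and -0.07 (1.98th percentile), as did mRNA-binding protein genes at -0.02 in each (0.05th and 0.03th percentiles). Histones, the lowest list in the MKRN1-labelled RIP, also lay below input in both, at -0.02 (0.82th percentile) and -0.19 (0.00th percentile). Gmnn, an inhibitor of replication licensing, was 0.92 and 1.31 above input in the FLAG:Ctrl and IgG RIPs, and Rfc4 was 0.86 and 0.85 above it. These differences share the control RIP arrays with the comparisons to the MKRN1-labelled RIP, which ties the signs of the 2 sets.

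The 2 control RIPs differed least of the pairs compared. Only 20 genes were at least 2-fold higher in the FLAG:Ctrl RIP and 32 in the IgG RIP. AF067061 was -5.68 in the FLAG:Ctrl RIP relative to the IgG RIP, Eif4a3l1 -3.94, Pramel19 -3.19, Tcstv3 -3.01 and BC147527 -2.79. The FLAG:Ctrl RIP values of Eif4a3l1, Pramel19 and BC147527, from 3.92 to 4.35, lie below the level filter, so these sizes and their order are uncertain; raised to it, the differences were -2.25, -1.35 and -1.38. At the other end were the proteoglycan gene Srgn at 1.56 (1.12 with values raised, which puts it below the others named here), the endocytic adaptor gene Dab2 at 1.42 (0.69 with the median over its probe sets), Rny1 at 1.39, Timm21 at 1.35 and the signalling ligand gene Bmp4 at 1.34. These RIPs came from different lysates with different antibodies, so they are not replicates of each other.

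The 2 inputs compared steady-state RNA of the lines. In the FLAG:MKRN1 input 101 genes were at least 2-fold higher and 91 lower than in the FLAG:Ctrl input. AF067061 had log2 values of 10.94 and 3.88, and Snora7a of 10.18 and 5.69. Pramel19, of the PRAME-like family, was higher by 2.70, Gm9958 by 2.45, 1700019A02Rik by 2.31 and Snord16a by 2.28. All 6 lay below the level filter in the FLAG:Ctrl input, so the sizes and their order are uncertain; raised to it, the differences were 5.18 for AF067061, 4.42 for Snora7a, 1.27 for Pramel19, 1.66 for Gm9958, 1.39 for 1700019A02Rik and 1.67 for Snord16a. Lowest were 6720489N17Rik at -2.91, Marchf11 at -2.36 (-1.18 with the median over its 2 probe sets), the tetraspanin gene Tspan5 at -2.24, Nynrin at -2.12, Ndufa4l2 at -2.09 and Tatdn3 at -2.02. Between the control RIPs of the same lysates, AF067061 again differed by 5.68, the FLAG:MKRN1 lysate being higher, and Marchf11 by -0.24 and Tatdn3 by -0.64, while Tspan5 and Ndufa4l2 differed by 0.00. Snord16a at -0.51, 6720489N17Rik at 0.42 and Nynrin at 0.84 went the opposite way there. The 3 probe sets of Nynrin ranged from -2.12 to 0.42 between inputs, and with their median the difference was 0.21, of the opposite sign.

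Several members of the fixed lists differed between the inputs and, in the same direction, between the control RIPs of the 2 lysates. Lefty1, a Nodal antagonist gene, was 1.69 higher in the FLAG:MKRN1 input and 1.73 higher in the IgG RIP than in the FLAG:Ctrl RIP. Bmp4 differed by -1.57 and -1.34, Myc by -1.25 and -1.15, Klf4 by -1.17 and -1.02, Sparc by -1.14 and -1.03, and Dab2, a primitive endoderm marker, by -1.75 (-0.89 with the median over its probe sets) and -1.42. Of the 192 genes 2-fold apart between inputs, 147 (76.6%) had the same sign between the control RIPs, 23 of these at 2-fold, and none was 2-fold apart with the opposite sign. Across genes r was 0.40 for these 2 differences, which share no array; genes are not independent replicates.

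Among lists, histones were higher in the FLAG:MKRN1 input, with a median of 0.28 (100th percentile), although no member reached 2-fold and the median between the control RIPs was 0.00 (61.2th percentile). Oxidative phosphorylation genes differed by -0.09 (0.12th percentile) and by 0.00 between the control RIPs. Primitive endoderm (10.8th percentile), trophectoderm (8.56th), mesoderm (57.2th) and ectoderm genes (96.6th) stayed within the range between inputs; between the control RIPs the first 2 lay at -0.13 (0.28th percentile) and -0.19 (0.06th percentile). Immediate early genes lay at -0.14 (1.27th percentile) with Myc and Spry4 2-fold lower, endoplasmic reticulum stress genes at -0.13 (1.90th percentile) and glycolysis genes at -0.12 (2.22th percentile). Between the control RIPs those 3 lists lay at -0.13, -0.12 and -0.14, at or below the 0.33th percentile. Proteasome and secreted genes lay at -0.08 (1.42th percentile) and -0.09 (1.79th percentile) between inputs, but at 0.01 (72.8th percentile) and -0.00 (23.8th percentile) between the control RIPs. Under another filter or summary of probe sets, immediate early (16.9th percentile), endoplasmic reticulum stress (17.4th), secreted (9.45th) and glycolysis genes (6.70th) lay within the range between inputs. The pluripotency list lay at -0.07 (9.51th percentile) between inputs and at -0.12 (0.05th percentile) between the control RIPs. Feeder fibroblast markers lay at 0.02 (74.5th percentile) and -0.16 (3.06th percentile).

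**Figure D3:**
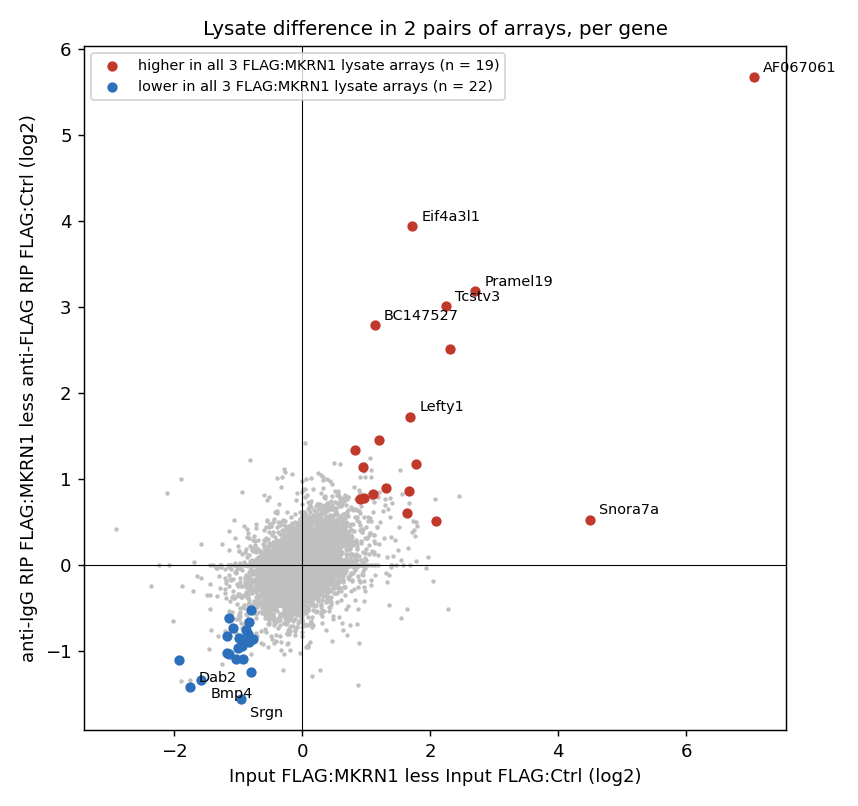
Each point is 1 gene, with its log2 difference between the FLAG:MKRN1 and FLAG:Ctrl inputs on the x axis and between the IgG RIP of FLAG:MKRN1 lysate and the FLAG:Ctrl RIP on the y axis. Red points are the 19 genes higher, and blue points the 22 genes lower, in all 3 arrays of FLAG:MKRN1 lysate than in both arrays of FLAG:Ctrl lysate by at least 0.5; AF067061 lies at 7.06, against an input value below the level filter, and 5.68.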

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

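The tests of raised nonspecific signal, carry-over, small nucleolar RNA in the lysate and chance input differences were chosen only after the pattern was seen, as were the RNA classes by symbol, the look at gene spans and the way the trend with signal level was removed; the test of carry-over replaced earlier ones that were void. The tests of compressed signal, of RNA bound to the protein and of feeder fibroblasts were written beforehand.

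Probe sets outside the gene comparison, those with several symbols or none, also met the call rule in the MKRN1-labelled RIP. Of 4902 such probe sets at or above the level filter, 320 (6.53%) were at least 2-fold higher than in both control RIPs and above input, against 21 in the FLAG:Ctrl RIP and 24 in the IgG RIP, and 480 were lower. They were picked out because the report's comparisons do not use them and the count lay above that of the control RIPs.

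The MKRN1-labelled RIP stood apart from all other arrays, with 742 called genes. Its median difference from the FLAG:Ctrl RIP ran from 0.18 in the dimmest of 8 bins to -0.39 in the seventh. With that trend removed, 344 genes were lower than in both control RIPs, 340 of them among the 617 before. The trend therefore goes with part of the lower calls, and a narrower range acting through it is argued against as the whole cause. In a control RIP at most 11 were lower. Such calls need 2-fold between the control RIPs, where only 20 and 32 genes lay that far apart as deposited. Only bin medians were shifted, so other compression or noise on this array was not tested and stays open. Loss of longer RNA by fragmentation or in amplification stays open and has no test here, because transcript lengths were not used; an exploratory look at the spans of genes in the RefSeq table, which are not transcript lengths and for which no value is given, had longer genes lower on this array. Raised nonspecific signal remains a candidate explanation for part of the higher calls, because 35 kept olfactory receptor genes, which stem cells hardly use, lay at 0.34 (99.96th percentile) against the FLAG:Ctrl RIP and 0.26 (98.4th percentile) against the IgG RIP. Against its own input the class lay at 0.21, within the range (93.7th percentile). In the FLAG:Ctrl and IgG RIPs it lay below input, at -0.14 and -0.12, so part of the gap goes with the control RIPs. RNA bound to the FLAG:MKRN1 protein, the biological explanation the design names, cannot be told apart from a feature of this RIP, because there was 1 array of its kind.

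Small nucleolar RNAs with Snora, Snord and Scarna symbols were 17 of the 125 genes called higher, with 3 of the 39 kept called lower. Their quartiles ran from -0.46 to 1.85 against the FLAG:Ctrl RIP and from -0.53 to 1.70 against the IgG RIP. Carry-over of lysate RNA was expected to leave at least 75% of the class within 2-fold of the input of the same lysate, and 41.0% were. The bound set against carry-over, a median at least 2-fold above that input, was not met either, with a median of 0.12. Of the 39, 12 were at least 2-fold above it and 11 at least 2-fold below. Members went both ways, so the median decides nothing and carry-over stays open for part of the class. More small nucleolar RNA in the FLAG:MKRN1 lysate stays open as part of the difference from the FLAG:Ctrl RIP. The class lay 0.56 higher between the inputs. Its median over the FLAG:Ctrl RIP was 0.10 in the IgG RIP and 1.20 in the MKRN1-labelled RIP. Both RIPs of the FLAG:MKRN1 lysate share its level, so a lysate difference alone would not set them apart. Of the 39, 26 (66.7%) were higher in the MKRN1-labelled RIP than in the IgG RIP of the same lysate. That share lay between the bounds of 60% and 75% set for the test of this explanation. A test on the median against the IgG RIP (0.71, 100th percentile) was put in its place after this result was seen and then withdrawn, since 13 members were not higher. In the IgG RIP the class lay at -0.60 against the same input.

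The arrays of the 2 lysates differed in RNA. Of genes 2-fold apart between the 2 inputs, 76.6% had the same sign between control RIPs, which share no array with the inputs. Chance differences arising separately in each gene would give about 50% or less, since 17.8% of kept genes had equal values in the control RIPs. The share argues against that form of chance only. Genes vary together and there were no replicates, so chance differences shared by many genes were not tested and stay open. Of 22 feeder fibroblast markers on the array, 6 were kept. The others, among them Dcn, Lum, Postn and Col6a3, had a mean below the level filter. Feeder fibroblasts left in the FLAG:Ctrl culture stay open: 6 marker genes lay at the 74.5th percentile between inputs and at the 3.06th between the control RIPs. The bound set beforehand, above the 2.5th percentile in both, would have excluded them, but with 6 genes a value of 3.06 is too close to it, so the bound was moved to the 10th percentile after these values were seen. The collagen genes Col1a1 (6.88 in the FLAG:Ctrl and 6.78 in the FLAG:MKRN1 input) and Col3a1 (5.81 and 5.74) differed little, S100a4 was lower in the FLAG:Ctrl input (6.29 and 7.01) and Thy1 higher (9.88 and 8.89). Differences between clones and an effect of MKRN1 are confounded with the lysate and were not tested.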

How the results depend on the processing

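Removal of the trend with signal level and the raising of values below the level filter to it were chosen after seeing the data. Over all alternatives, 105 recomputed counts stayed within 1.5 times the value in the report and 53 did not. A stricter filter or another threshold changes by construction how many genes can pass; for the other changes the cause was not tested. With each array centred, 190 genes were called higher and 405 lower; 306 were higher and 529 lower than in the FLAG:Ctrl RIP; 68 were higher in the FLAG:Ctrl RIP and 98 in the IgG RIP than in their inputs. All 125 higher and 405 of the 617 lower calls were shared with the main setting. With the filter at the 75th percentile, 59 genes were called higher; the MKRN1-labelled RIP had 87 higher than the FLAG:Ctrl RIP, 84 than the IgG RIP and 161 than its input. The FLAG:Ctrl RIP then had 63 higher and 22 lower than input, the IgG RIP 93 and 26, the FLAG:Ctrl against the IgG RIP 11 and 15, and the inputs 39 and 43. At 1.5-fold, 548 genes were called higher and 1654 lower. The counts higher and lower were then 778 and 2142 against the FLAG:Ctrl RIP, 735 and 2062 against the IgG RIP, 1068 and 1640 against input, 693 and 195 for the FLAG:Ctrl RIP and 824 and 196 for the IgG RIP against input, 164 and 184 between the control RIPs, and 404 and 455 between inputs. At 4-fold, 16 were called higher and 23 lower, so higher genes made up 41.0% of the calls. In the same order the counts were 26 and 40, 19 and 32, 26 and 42, 2 and 5, 3 and 5, 0 and 6, and 10 and 6. With the trend with signal level removed, 344 were called lower, 484 were lower than in the FLAG:Ctrl RIP and 500 than in the IgG RIP. With values below the level filter raised to it, 124 were called higher and 609 lower. Among genes named by score or input difference and the makorin genes, 132 values moved by at most the SD of 0.243 between the control RIPs, 11 moved by more, 7 of them with dim values raised, and 1 reversed. For the ends of the other comparisons 142 values stayed within that SD and 18 did not, 13 of these with dim values raised, and for list members, by score or input difference, 741 did and 38 did not. Of 40 list members called, apart from those named by score, 10 were short of 2-fold with arrays centred, 13 after quantile normalization, and 1 each with the median over probe sets and with dim values raised. The median over probe sets gave Snora21 a score of 3.37, Depdc1a 1.34 and Rbbp6 -1.80, and input differences of -1.18 for Marchf11 and, reversed, 0.214 for Nynrin. Of 50 list medians outside the range in the 7 comparisons, 38 to 47 stayed on the same side per alternative run for lists, 0 moved to the opposite side, and 0 to 8 others came to lie outside. Thresholds and other uses of the control RIPs and inputs do not apply to lists. The alternatives used 2000 random lists. Signs of list medians within about 0.2 of 0 depended on scaling, as given for ribosomal and pluripotency genes. The floor planned for a linear table was not run, because the table is on a log2 scale. No paired analysis was possible because there were no replicates to pair; differences from the input of the same lysate are in the report. The counts higher and lower in the control RIPs by the call rule were 90 and 32 (FLAG:Ctrl) and 75 and 24 (IgG) at 1.5-fold, and 0 and 3, and 0 and 0, at 4-fold. Signal over background limits dim genes: the lowest kept genes lie near 5.76, and no detection call was used here.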

Other observations

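The tests of 2-cell-like cells and of a repeated family, the raising of dim values, the gap of 0.5 and the gene classes by symbol were chosen after the data were seen, as were the genes named for that gap.

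Genes that separated the 2 lysates in every array form a short list. By a gap of 0.5, 19 genes were higher and 22 lower in all 3 FLAG:MKRN1 arrays than in both FLAG:Ctrl arrays. Higher genes included the thyrotropin-releasing hormone gene Trh, at 12.26 in the FLAG:MKRN1 and 11.35 in the FLAG:Ctrl input, the cell-surface gene Cd24a at 11.19 and 9.99, Lefty1 at 9.59 and 7.90, and Marcks, a protein kinase C substrate gene, at 9.57 and 8.62. Lower genes included Bmp4 at 8.83 and 10.41, Sparc at 10.18 and 11.31, Klf4 at 7.65 and 8.82, the imprinted gene Peg10 at 11.96 and 12.90, the receptor signalling inhibitor gene Spry4 at 8.43 and 9.51, the hypoxia factor gene Epas1 at 8.38 and 9.21, and the germline factor gene Mael at 8.91 and 9.71. Of the 10 splits of the 5 arrays into 3 and 2, this one gave 41 genes and the others between 1 and 93, the largest being the RIPs against the inputs, so the count alone does not set the lysates apart.

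MicroRNA genes lay higher in the MKRN1-labelled RIP, as did classes that stem cells hardly use. The 61 kept lay at medians of 0.61 against the FLAG:Ctrl RIP and 0.48 against the IgG RIP, 57 and 55 of them above 0, with 6 called higher and 1 lower. In the control RIPs the class lay below input, at -0.22 and -0.15. Defensin genes lay at 0.70 and 0.58 over 6 genes, 5 of them above 0 in each, and keratin-associated protein genes at 0.44 and 0.29, with all 11 above 0 in each, so the shift was not particular to microRNA genes. Zinc finger genes of the Zfp series had medians of -0.07 and -0.08 over 257 genes, with 19 called lower and 3 higher; with each array centred the medians were 0.09 and 0.07.

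Tcstv3, which separates the lysates, is a member of the fixed list for the 2-cell-like state, a rare state of stem cell cultures. More 2-cell-like cells in the FLAG:MKRN1 culture stays open as a hypothesis: over all genes, with no filter on level, the 11 measured members had medians of 0.30 between inputs and 0.69 between the control RIPs, both at the 100th percentile, but 9 of them had a mean below the level filter. With values below that level raised to it the medians were 0 at the 50th percentile in both. That setting cannot decide the question, because 6 of the 11 lay below the level on all 5 arrays, so the median could not rise above 0. In it 3 and 2 members were above 0, among them Gm5662 at 0.96 and 1.94 and Tcstv3 at 1.78 and 3.01. The list was fixed earlier, but the filter was dropped after values of Tcstv3 and AF067061 had been seen. Whether probe sets of 1 repeated family were counted several times cannot be told apart from separate changes for AF067061, BC147527 and Tcstv3, since only 3 other annotated genes lie between the outermost of them and probe sequences were not used here.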
